A study of Mus musculus with 12 samples.

How the data were processed

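RNA from 12 mouse whole hearts was sequenced, in 4 groups of 3. Per the labels, Flox mice carried loxP-flanked Cited4 alleles, and KO mice came from crossing them with mice expressing cre under the aMHC promoter, which removes the gene in cardiomyocytes. Both genotypes were kept sedentary or given voluntary wheel running for 8 weeks. Hearts were frozen, RNA was taken with Trizol, ribosomal RNA was depleted with a RiboZero kit and libraries were built with an NEB kit, per the labels' protocols. The samples hold no group with cre and intact Cited4 alleles, so the KO label carries both the loss of Cited4 and the transgene. The labels say that the samples came from mice and not which animal gave which sample, so p-values measure the spread between these samples.

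Groups were taken from the genotype and treatment words of the labels. The bracketed codes in the titles carry a letter that reads the other way for the treatment (E with the sedentary word, S with the exercise word), so the treatment is called labelled exercise or labelled sedentary throughout. If the codes and not the words were right, each exercise direction, that averaged over genotype included, and the interaction would turn. The 2 genotype comparisons within a treatment would exchange names, and KO over Flox averaged over treatment would stay as it is.

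The deposited table holds estimated counts per gene symbol, not scaled between libraries. FastQC and Salmon, a program that estimates counts per transcript, are named in the submitters' processing notes with no version, as are the builds mm9 and mm10 with no role. The annotation release, the strand setting and the step from transcripts to genes are not given in the sources used here. Among entries with a count in any library, 21.6% to 26.4% of a library's values were not whole, and estimated counts were rounded to whole numbers before testing. Salmon splits reads between near-identical sequences, so values of paralogs with near-identical copies (Hba-a1, Hspa1a), of mitochondrial genes with nuclear copies or overlapping ends (mt-Atp8 with mt-Atp6), and of genes with antisense partners are uncertain to that extent.

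Of 55874 entries in the table, 1696 named cloning vectors, phages, adaptors or linkers. They took between 3.87e-05% and 0.186% of a library's counts and were left out of library sizes and tests, which used the other 54178 entries. Library totals ran from 17465401 to 20467260 counts, and the 13 mitochondrially encoded genes took 21% to 27.2% of them. Levels are given as CPM, the counts of a gene scaled to a common library size, and intervals on counts cover counting error only. Replicate pairs differed by a chi-square of 17.1 to 84.7 per degree of freedom over genes, so no pair looked like a single library entered again. Xist was at or below 0.776 CPM in all libraries.

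Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, a cell-means model over all 12 libraries, glmQLFit with robust estimation, glmQLFTest and Benjamini-Hochberg adjustment at 0.05. The filter left 15226 genes. One fit over the 4 groups shared the estimate of spread, since a group had 3 hearts. Comparisons were exercise over sedentary labels in Flox and in KO, KO over Flox in each treatment label, the interaction (the difference in KO minus the difference in Flox), and the average over the other factor. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are means ± SD over 3 libraries on TMM-scaled library sizes.

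Before the data were examined, 33 gene lists were fixed for cardiac regulators and stress genes, metabolism, growth and cell cycle, matrix, calcium handling, the clock, stress responses, cell types of the heart, neighbours of Cited4 on chromosome 4, and sex-linked genes. They were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation, and fry, which asks whether a list moves on balance one way without comparing it with other genes, were run beside it. With an estimated correlation no list passed in any comparison. Fry passed adipocyte markers for exercise labels in KO (adjusted p = 0.00851), and 3 lists for KO over Flox under the sedentary label: adipocyte (adjusted p = 0.0147), Schwann and neuronal (0.0347) and p53 targets (0.0423). For each list passing the preset-correlation test, the median and mean of the members' log2 fold changes and the test had one sign. The difference of the list mean log2 CPM had the other sign for calcium handling under the sedentary label (0.03) and for no other passing list. Each of the 12 libraries was left out in turn, and a list whose call was then lost is named in the text with the libraries concerned, the largest adjusted p and the median at that p.

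Named genes followed a rule fixed in advance: Cited4, up to 8 genes per direction past the threshold with at least 1 CPM on average and no overlap between the groups' libraries, 4 members by smallest p from each list passing camera, members past the threshold in other lists, and otherwise 4 genes per direction by smallest p. Some were left out for length. Named after their values were seen were Arntl, Npas2, Dbp, Per2, Per3, Ciart and Tef for exercise labels in Flox, Bhlhe40, Nfil3, Dbp and Arntl for exercise labels in KO, Map1b, Serpinf1 and Atp2b4 for genotype under the sedentary label, Arntl, Npas2 and Nfil3 for the interaction, Cyp2e1 for the genotype average, and Ucp1 and Car3 as members of the adipocyte list. Positions were looked up by symbol in GENCODE vM21 on GRCm38 (mm10), which may differ from the annotation behind the counts.

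Alternatives fixed in advance were DESeq2's size factors, no filter on low counts, a mean CPM of 1 or more, DESeq2 1.42.0 (Wald test), the replicate number as a block, the atrial marker mean as a covariate, the compared groups alone, and leaving out each library. Library totals without TMM, a term for libraries with vector reads, those libraries alone, the atrial covariate for lists, and both terms together were added after the data had been seen. Library totals alone moved the median of all genes by 0.18 (log2) for genotype under the sedentary label, -0.15 for exercise labels in KO, -0.16 for the interaction and 0.11 for the genotype average. No passing list's median changed sign under DESeq2's size factors, under library totals, or relative to that shift. Only signs were compared. A shift of 0.18 is not small beside list medians such as -0.32 for the respiratory chain under the sedentary label, so their size depends on the scaling.

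The tests were tried on simulated counts with 200 changed genes. For exercise labels in Flox, 54% of genes changed by a log2 of 1 and 84.8% of those changed by 2 were recovered, with 8 false calls among 146. The shares were 60% and 84.8% for genotype under the sedentary label (9 false of 153), 72% and 85.9% for exercise labels in KO (5 of 162), and 65.3% and 86.6% for genotype under the exercise label (9 of 157). They were 78.4% and 94.8% for the genotype average (9 of 177), and 81% and 98% for the exercise average (17 of 195). The interaction was not simulated. Shifting the clock list by a log2 of 0.5 in simulated counts for exercise labels in Flox gave a camera adjusted p of 1.01e-12 and no other list passed. Each gene was simulated independently, with no shared variation such as atrial share or library batch would give. The simulations therefore do not test how the list calls, or the numbers of genes, behave when genes vary together as in the real libraries.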

Results

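Whole-heart RNA was compared between mice with intact floxed Cited4 alleles (Flox) and mice in which cre driven by the cardiomyocyte aMHC promoter deletes the gene (KO). Each genotype was labelled sedentary or labelled exercise for 8 weeks of sedentary housing or voluntary wheel running. There were 3 libraries in each of the 4 groups, with 17465401 to 20467260 counts per library. Of the genes in the table, 15226 had enough counts to be tested. Cited4 encodes a transcriptional co-regulator that binds CBP and p300. The title of the series states an interest in whether the heart needs it for growth in response to exercise and for the formation of cardiomyocytes. The largest component of variation between libraries took 30.6% of the variance and ordered the libraries much as their atrial markers did. The mean of the 19 atrial cardiomyocyte markers was 3.86 ± 1.83 log2 CPM in Flox labelled sedentary, 4.07 ± 2.16 in Flox labelled exercise, 7.10 ± 1.38 in KO labelled sedentary and 4.88 ± 2.03 in KO labelled exercise (SD, n = 3 each).

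Cited4 transcripts were nearly absent from every KO library. The gene lies on chromosome 4 at 120666572 to 120667820 on the forward strand (GRCm38) and has 1 exon. Flox libraries labelled sedentary held 276, 192 and 295 Cited4 counts and those labelled exercise 406, 261 and 431, against 5, 2 and 0 in KO labelled sedentary and 3, 0 and 0 in KO labelled exercise. Relative to library size, the KO libraries together held 0.484% of the Flox level (exact 95% interval 0.232 to 0.893, counting error only). Under the sedentary label the share was 0.788% (0.316 to 1.63) and under the exercise label 0.259% (0.0534 to 0.760). The log2 difference averaged over treatment was -7.67 ± 0.41 (SE; edgeR, adjusted p = 7.79e-06). The genotype words of the labels matched the gene in all 12 libraries. In Flox hearts Cited4 stood at 13.8 ± 3.26 CPM under the sedentary label and 20.3 ± 5.67 under the exercise label. This log2 difference of 0.56 ± 0.33 did not pass (adjusted p = 0.735). With 7 and 3 counts in the KO groups, no fold between treatments was drawn there. Of the 10 tested neighbours of Cited4 on chromosome 4, none passed for the genotype average (edgeR; list median 0.03, camera adjusted p = 0.623), 1 had an unadjusted p under 0.05, and none passed adjusted over the list alone.

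**Figure D1:**
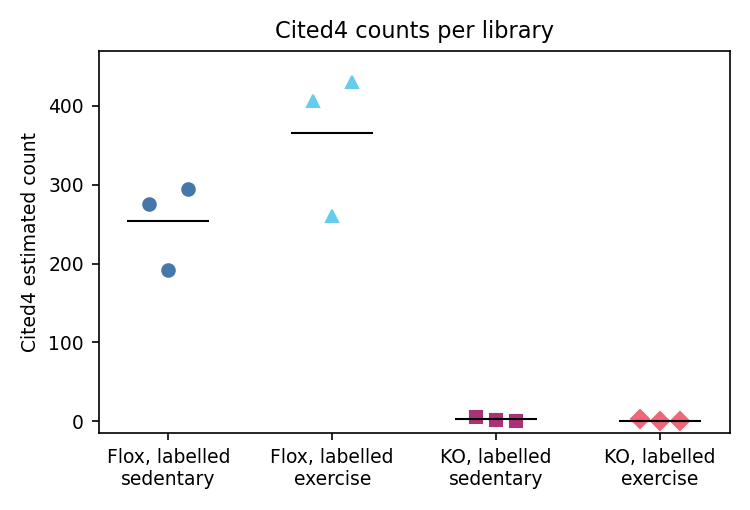
Estimated count of Cited4 in each library, by group; each point is 1 library and each horizontal line the mean of its 3 libraries. Flox libraries hold 192 to 431 Cited4 counts and KO libraries 0 to 5.

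Under the sedentary label, KO hearts carried more RNA of genes typical of fat cells than Flox hearts. Cidec, a lipid droplet protein of adipocytes, stood at 11.5 ± 4.22 CPM against 0.284 ± 0.277 (log2 difference 5.36 ± 0.57, adjusted p = 0.00370), and Adipoq, the hormone adiponectin, at 10.9 ± 5.16 against 0.258 ± 0.137 (5.40 ± 0.66, adjusted p = 0.00900). Cyp2e1, a cytochrome P450, rose from 0.517 ± 0.327 to 15.2 ± 3.72 CPM. Scd1, the desaturase that makes monounsaturated fatty acids, rose from 19.7 ± 4.88 to 129 ± 57.6 CPM. Prkar2b, a regulatory subunit of protein kinase A, rose 10.2-fold and Cdo1, which oxidises cysteine, 8.63-fold. Clstn3, a calsyntenin, rose 7.68-fold and Cebpa, a transcription factor of adipocyte differentiation, 2.79-fold. Also higher were Myl9, a smooth muscle myosin light chain (3.90-fold), and Phlda3, a p53 target that restrains AKT (1.93-fold). Among the genes that fell besides Cited4 was Ttll1, a tubulin glutamylase subunit, from 54.2 ± 6.81 to 28.5 ± 3.52 CPM (-0.93 ± 0.13, adjusted p = 0.0156). In all, 19 genes passed (edgeR), 16 higher and 3 lower in KO. Others that rose were the microtubule protein gene Map1b (1.93-fold), Serpinf1 (1.87-fold), the calcium pump gene Atp2b4 (1.58-fold) and the low-count Retn and Acvr1c. Positions on GRCm38 are chromosome 6, 113424634 to 113435760 for Cidec, chromosome 16, 23146536 to 23158028 for Adipoq, chromosome 7, 140763739 to 140774987 for Cyp2e1, and chromosome 15, 83483769 to 83510893 for Ttll1. The count was 479 without KO labelled sedentary 1, 43 without KO labelled exercise 3 and 35 without KO labelled exercise 2. It was 11 without Flox labelled sedentary 1, 6 without Flox labelled sedentary 3, 7 without KO labelled sedentary 3 and 2 without Flox labelled sedentary 2. With the atrial marker mean as a covariate it was 3; Cidec stood at 5.77 ± 0.72 (adjusted p = 0.0313) and Adipoq at 5.31 ± 0.88 (adjusted p = 0.175), with larger standard errors than before.

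Among the lists fixed in advance, adipocyte markers were higher in KO under the sedentary label (camera adjusted p = 6.83e-13, median log2 difference 2.61; adjusted p = 0.131 with an estimated correlation). Of its 20 measured members 4 rose over all genes and none fell, while adjusted over the list alone 15 were higher and 1, Lpl, was lower. Genes of the nuclear-encoded respiratory chain were lower in all 70 measured members (median -0.32, camera adjusted p = 2.34e-21; adjusted p = 0.338 with an estimated correlation). None passed singly over all genes or adjusted over the list alone. Examples are the ATP synthase subunits Atp5k (-0.81 ± 0.23) and Atp5g3 (-0.51 ± 0.15) and the cytochrome oxidase subunit Cox5a (-0.45 ± 0.14). The 13 mitochondrially encoded genes were lower too (median -0.29, camera adjusted p = 5.97e-05; adjusted p = 0.338 with an estimated correlation). Adjusted over the list alone 3 were lower and over all genes none, with mt-Atp8 at -1.06 ± 0.25. Fatty acid oxidation genes were lower in 32 of 35 members (median -0.41, camera adjusted p = 6.83e-13; adjusted p = 0.338 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Among them were Etfb (-0.48 ± 0.13), Acadvl (-0.46 ± 0.15) and Lpl (-0.49 ± 0.14). The list mean fell in KO labelled sedentary 2 and 3 (7.35 and 7.3 log2 CPM) and hardly in 1 (7.84, Flox 7.85 to 7.91). Glycolysis genes had a median of -0.17 (camera adjusted p = 0.00101; adjusted p = 0.402 with an estimated correlation), 1 higher and 3 lower adjusted over the list alone. Pfkfb1 was at -1.68 ± 0.36 and Ldhb at -0.49 ± 0.14. The glycolysis mean also fell in 2 and 3 (7.95 and 7.9) and hardly in 1 (8.18, Flox 8.18 to 8.24). Regulators of mitochondrial biogenesis were lower in 19 of 20 members (median -0.19, camera adjusted p = 0.000131; adjusted p = 0.396 with an estimated correlation); the difference of their list mean went from -0.23 to -0.37 without KO labelled sedentary 1 and to -0.14 without KO labelled sedentary 3. The respiratory chain mean differed by -0.33 ± 0.13 (SE) without the atrial covariate and -0.20 ± 0.16 with it. Fatty acid oxidation differed by -0.39 ± 0.18 and -0.20 ± 0.21, and adipocyte markers by 2.59 ± 0.35 and 2.78 ± 0.45.

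Contractile genes were lower, and matrix genes higher, in KO under the sedentary label. Cardiomyocyte markers were lower in 24 of 25 members (median -0.33, camera adjusted p = 2.43e-08; adjusted p = 0.301 with an estimated correlation), with none passing over all genes and 2 adjusted over the list alone. The ventricular myosin light chains Myl2 (-0.83 ± 0.19) and Myl3 (-0.79 ± 0.23) led them. Calcium-handling and ion channel genes had a median of -0.20 (camera adjusted p = 0.000131; adjusted p = 0.396 with an estimated correlation), but the list mean was 6.95 ± 0.12 log2 CPM in KO and 6.92 ± 0.28 in Flox. That difference ran from -0.11 without Flox labelled sedentary 1 to 0.17 without Flox labelled sedentary 3. The L-type calcium channel gene Cacna1c was at -0.71 ± 0.19. Matrix genes were higher in 33 of 36 members (median 0.56, camera adjusted p = 3.03e-12; adjusted p = 0.301 with an estimated correlation), none over all genes and 10 adjusted over the list alone. Among them were the proteoglycan Bgn (0.81 ± 0.19) and the collagen Col5a2 (0.83 ± 0.24). Fibroblast markers had a median of 0.61 (camera adjusted p = 1.42e-06; adjusted p = 0.338 with an estimated correlation), with 8 of 19 higher adjusted over the list alone and none over all genes. These included Mfap5 (0.79 ± 0.18) and Dpt (0.73 ± 0.21), both matrix proteins, Pcolce, which helps process procollagen (0.69 ± 0.14), and Tcf21, a transcription factor of cardiac fibroblasts (0.83 ± 0.24). Fetal and stress genes of the heart were higher (median 0.76, camera adjusted p = 0.000663; adjusted p = 0.175 with an estimated correlation), 8 higher and 1 lower adjusted over the list alone and none over all genes. Ankrd1, a stretch-responsive repeat protein, was at 0.92 ± 0.19, the stress cytokine Gdf15 at 1.62 ± 0.41 and the matricellular Postn at 1.11 ± 0.32, while the myosin heavy chain Myh7b was at -0.72 ± 0.20. Immediate early (median 0.50, camera adjusted p = 0.00131), macrophage (0.51, 4.16e-05), Schwann and neuronal (0.30, 0.00188), mesothelial (1.47, 0.0166), skeletal muscle (1.30, 0.0326) and p53 target lists (0.13, 0.00731) were higher too. Their adjusted p with an estimated correlation was 0.457, 0.457, 0.131, 0.589, 0.389 and 0.175. The immediate early list rested on KO labelled sedentary 3, without which its median was 0.09 (camera adjusted p = 0.464); Egr3 stood at 2.46, 1.39 and 8.99 CPM in KO labelled sedentary. Fetal and stress genes no longer passed without KO labelled sedentary 1 (adjusted p = 0.0516, median 0.65), and p53 targets without KO labelled sedentary 1 (adjusted p = 0.108, median 0.12). Mesothelial markers no longer passed without Flox labelled sedentary 1 or 2 or KO labelled sedentary 3 (adjusted p up to 0.117, median 1.06), and skeletal muscle markers without Flox labelled sedentary 2 or 3 or KO labelled sedentary 3 (adjusted p up to 0.0786, median 0.95). The other 13 of 18 lists passed whichever library was left out. Among the members were the transcription factor Egr3 (1.77 ± 0.61), the adhesion molecule Ncam1 (1.38 ± 0.42), Dbh, which makes noradrenaline (1.55 ± 0.53), the keratin Krt18 (1.78 ± 0.85) and the calcium pump Atp2a1 (1.63 ± 0.51). All 19 atrial markers were higher (median 2.33, camera adjusted p = 3.05e-06; adjusted p = 0.396 with an estimated correlation). With the atrial marker mean as a covariate, the difference of the matrix list's mean went from 0.64 ± 0.22 to 0.37 ± 0.24 and that of the cardiomyocyte list from -0.36 ± 0.11 to -0.18 ± 0.10.

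**Figure D2:**
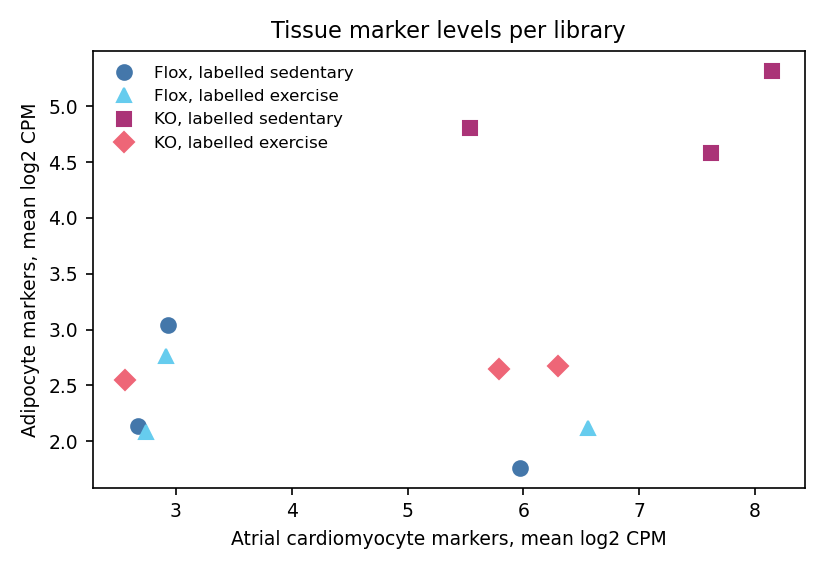
Mean log2 CPM of the adipocyte markers (vertical) against that of the atrial cardiomyocyte markers (horizontal); each point is 1 library, with shape and colour by group. The KO libraries labelled sedentary have adipocyte means of 4.58 to 5.32, above the 1.76 to 3.04 of the other libraries.

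Under the exercise label, Cited4 was the single gene that differed between KO and Flox (edgeR, adjusted p = 0.000228; 1209 genes at an unadjusted p under 0.05; DESeq2 called 10). The count was 2 without Flox labelled sedentary 1, Flox labelled sedentary 2 or Flox labelled exercise 1. Among the genes with the next smallest p, none passing, the D-type cyclin Ccnd2 stood at 154 ± 17.9 CPM in KO against 88.6 ± 4.03 in Flox (0.79 ± 0.12, adjusted p = 0.123), and the proton pump subunit Atp6v0e2 at 24.6 ± 3.76 against 10.6 ± 1.82 (1.22 ± 0.20, adjusted p = 0.123). The kinase gene Sgk1 was at -0.65 ± 0.12 and the sterol-binding protein gene Osbpl3 at 0.62 ± 0.11 (adjusted p = 0.222 each). Eps8l1 was at -2.47 ± 0.45 and Fam214b at 0.38 ± 0.09, also without passing.

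Of the lists, 3 were higher and 5 lower in KO under the exercise label, and none passed with an estimated correlation (smallest adjusted p = 0.833). Interferon response genes were lower in 32 of 34 members (median -0.40, camera adjusted p = 7.73e-09; adjusted p = 0.833 with an estimated correlation). Mx2, annotated as a polymorphic pseudogene, was at -0.81 ± 0.28, the RNA sensor Ddx58 at -0.43 ± 0.12 and the chemokine Cxcl9 at -0.84 ± 0.30. All 21 endothelial markers were lower (median -0.34, camera adjusted p = 9.47e-09; adjusted p = 0.833 with an estimated correlation), among them the angiopoietin receptor Tek (-0.33 ± 0.11), Ecscr (-0.50 ± 0.19) and Emcn (-0.31 ± 0.12). Neither list had a member passing over all genes or adjusted over the list alone. Heat shock genes had a median of -0.20 (camera adjusted p = 0.00867; adjusted p = 0.833 with an estimated correlation), 1 lower adjusted over the list alone. The co-chaperones Dnaja1 and Dnajb1 were at -0.50 ± 0.13 and -0.58 ± 0.17. Immediate early genes had a median of -0.24 (camera adjusted p = 0.0456; adjusted p = 0.833 with an estimated correlation), with the transcription factors Klf4 at -0.50 ± 0.14 and Klf2 at -0.62 ± 0.19. The respiratory chain list was lower in 63 of 70 members (median -0.18, camera adjusted p = 2.15e-05; adjusted p = 0.833 with an estimated correlation), with Cox7a1 at -0.44 ± 0.19 and Atp5j at -0.36 ± 0.16. Higher were the clock (median 0.54, camera adjusted p = 0.0193), regulators of mitochondrial biogenesis (0.11, 0.0208) and calcium handling (0.17, 0.00867), each at an adjusted p = 0.833 with an estimated correlation. Members included the clock repressors Bhlhe41 (0.89 ± 0.26) and Cry2 (0.59 ± 0.20). Others were the nuclear receptor Esrrb (0.56 ± 0.17), the mitochondrial transcription factor Tfb2m (0.39 ± 0.10), the potassium channel Kcnh2 (0.42 ± 0.18) and the sodium-calcium exchanger Slc8a1 (0.60 ± 0.26). Clock genes did not all move one way. Nfil3 stood lower in KO, at 5.31, 5.58 and 11.5 CPM against 11, 21.5 and 16.6 in Flox. The number of lists was 4 without Flox labelled exercise 3 and 14 without KO labelled exercise 3. Only 2 of the 8, interferon response and endothelial markers, passed whichever library was left out. The respiratory chain no longer passed without Flox labelled exercise 3 or KO labelled exercise 3 (adjusted p up to 0.509, median -0.04), and mitochondrial biogenesis without Flox labelled exercise 2 or 3 or KO labelled exercise 1 (adjusted p up to 0.194, median 0.10). Calcium handling no longer passed without Flox labelled exercise 3 or KO labelled exercise 1 (adjusted p up to 0.302, median 0.12), and the clock without Flox labelled exercise 2 or KO labelled exercise 2 (adjusted p up to 0.124, median 0.36). Immediate early genes no longer passed without Flox labelled sedentary 1, Flox labelled exercise 2 or 3 or KO labelled exercise 1 or 2 (adjusted p up to 0.245, median -0.16), and heat shock genes without Flox labelled exercise 1 (adjusted p = 0.272, median -0.07).

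Averaged over both treatment labels, 8 genes differed between KO and Flox, 5 higher and 3 lower (edgeR). Among the genes that fell besides Cited4 was Ttll1 (-0.64 ± 0.09, adjusted p = 0.0197). Phlda3 rose 1.63-fold (adjusted p = 0.0107), Atp6v0e2 1.95-fold (adjusted p = 0.0197) and Ccnd2 1.48-fold (adjusted p = 0.0315). Cidec (3.17 ± 0.40) and Cyp2e1 (2.87 ± 0.35) rose at adjusted p = 0.0108 each, with 5.36 and 4.85 under the sedentary label and 0.99 and 0.89 under the exercise label; no gene passed the interaction (edgeR, smallest adjusted p = 0.279; 1505 at an unadjusted p under 0.05; DESeq2 called 47). Phlda3 lies on chromosome 1 at 135766119 to 135769136, Ccnd2 on chromosome 6 at 127125162 to 127152193 and Atp6v0e2 on chromosome 6 at 48537615 to 48541801. Leaving out Flox labelled sedentary 2 gave 4 genes, KO labelled sedentary 3 or KO labelled exercise 3 gave 5, and KO labelled sedentary 1 or KO labelled exercise 2 gave 34. With the atrial marker mean as a covariate the count was 2, Cited4 among them. Phlda3 then stood at 0.74 ± 0.11 (adjusted p = 0.0579), Ccnd2 at 0.56 ± 0.10 and Atp6v0e2 at 0.93 ± 0.17 (adjusted p = 0.272 each), against 0.71 ± 0.09, 0.57 ± 0.09 and 0.97 ± 0.14 without it.

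Averaged over the treatment labels, 10 lists were higher in KO and 7 lower. Under the exercise label the medians of matrix (-0.08), fibroblast (-0.04), macrophage (-0.19), Schwann and neuronal (-0.01) and cardiomyocyte lists (0.03) had the other sign than under the sedentary label (0.56, 0.61, 0.51, 0.30 and -0.33). Adipocyte markers were at 0.11 there against 2.61, atrial markers at 0.34 against 2.33, skeletal muscle markers at 0.22 against 1.30, fetal and stress genes at 0.22 against 0.76 and fatty acid oxidation at -0.03 against -0.41. Mitochondrially encoded genes were at -0.09 against -0.29. Interferon response genes were at -0.40 against -0.02 and endothelial markers at -0.34 against -0.14. The difference between the labels, which is the interaction, passed camera with the preset correlation for these lists except skeletal muscle (adjusted p = 0.466), and for none with an estimated correlation (smallest adjusted p = 0.428). The p53 target list had a median of 0.14 (camera adjusted p = 0.00339; adjusted p = 0.203 with an estimated correlation), 1 higher over all genes and 3 adjusted over the list alone. Phlda3, Gdf15 (1.08 ± 0.29) and Trp53inp1 (0.31 ± 0.09) had its smallest p. Fetal and stress genes had a median of 0.43 (camera adjusted p = 0.00147; adjusted p = 0.203 with an estimated correlation), with Ankrd1 1.72-fold higher without passing over all genes (adjusted p = 0.0803) and 2 higher adjusted over the list alone. The respiratory chain list was lower in 70 of 70 members (median -0.25, camera adjusted p = 6.30e-23; adjusted p = 0.467 with an estimated correlation), with Cox7a1 at -0.50 ± 0.13. Fatty acid oxidation genes had a median of -0.19 (camera adjusted p = 5.84e-09; adjusted p = 0.467 with an estimated correlation), with Etfb at -0.37 ± 0.09 and the thioesterase Acot1 at -0.88 ± 0.24. Interferon response genes had a median of -0.24 and endothelial markers one of -0.23 (camera adjusted p = 7.65e-06 each; adjusted p = 0.467 each with an estimated correlation). Iigp1 was at -0.40 ± 0.12, Sox18 at -0.46 ± 0.15 and Ly6c1 at -0.39 ± 0.13. Angiogenesis and hypoxia genes had a median of -0.16 (camera adjusted p = 0.0240; adjusted p = 0.507 with an estimated correlation), with Vegfa at -0.37 ± 0.12. The 13 mitochondrially encoded genes had a median of -0.16 (camera adjusted p = 0.000390; adjusted p = 0.467 with an estimated correlation), 4 lower adjusted over the list alone and none over all genes. Cardiomyocyte markers had a median of -0.13 (camera adjusted p = 0.00109; adjusted p = 0.467 with an estimated correlation), with Myl2 at -0.57 ± 0.13 and Tnni3 at -0.34 ± 0.11. Adipocyte (median 1.36), atrial (1.33), mesothelial (1.38), skeletal muscle (0.52), matrix (0.22), fibroblast (0.25), Schwann and neuronal (0.25) and macrophage markers (0.18) were higher at camera adjusted p from 5.73e-09 to 0.0271. With an estimated correlation their adjusted p ran from 0.203 to 0.823. Atp2a1 of the skeletal muscle list was at 1.77 ± 0.38. Whichever library was left out, 11 of the 17 lists passed. Without KO labelled exercise 3 the difference of the list mean went from -0.22 to -0.14 for fatty acid oxidation, from 0.28 to 0.18 for matrix and from -0.14 to -0.09 for cardiomyocyte markers. Angiogenesis and hypoxia genes no longer passed without Flox labelled sedentary 1 or 3, Flox labelled exercise 1 or 3, KO labelled sedentary 3 or KO labelled exercise 3 (adjusted p up to 0.395, median -0.13), and fibroblast markers without Flox labelled exercise 1 or KO labelled exercise 3 (adjusted p up to 0.0727, median 0.17). Macrophage markers no longer passed without Flox labelled sedentary 2, Flox labelled exercise 1 or 3, KO labelled sedentary 2 or 3 or KO labelled exercise 3 (adjusted p up to 0.626, median -0.03), and Schwann and neuronal markers without Flox labelled sedentary 3 or KO labelled sedentary 2 (adjusted p up to 0.0646, median 0.24). Mesothelial markers no longer passed without Flox labelled sedentary 1 or 2, Flox labelled exercise 1 or 3, KO labelled sedentary 3 or KO labelled exercise 3 (adjusted p up to 0.490, median 0.03), and skeletal muscle markers without Flox labelled sedentary 2 or 3, KO labelled sedentary 3 or KO labelled exercise 2 (adjusted p up to 0.114, median 0.51). With the atrial marker mean as a covariate 11 of the 33 lists passed, against 17 without it.

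In Flox hearts, genes of the circadian clock differed between the treatment labels. Dbp, a clock output transcription factor, stood at 200, 259 and 184 CPM in the libraries labelled sedentary and at 51, 7.57 and 24 in those labelled exercise. Arntl, the activator at the core of the clock, stood at 5.08, 0.84 and 5.75 against 22.5, 22.7 and 18.8. Of the 20 measured clock genes none passed over all genes, and 18 passed adjusted over the list alone, 5 higher and 13 lower under the exercise label (camera adjusted p = 8.48e-07, median -0.98; adjusted p = 0.309 with an estimated correlation). The repressors Bhlhe40 (-0.91 ± 0.13), Bhlhe41 (-1.40 ± 0.26), Cry2 (-0.90 ± 0.20), Per2 (-2.09 ± 0.64), Per3 (-1.76 ± 0.51) and Ciart (-3.11 ± 0.68) and the output factor Tef (-1.48 ± 0.35) were lower. Nfil3 (1.85 ± 0.40), which opposes Dbp, and Npas2 (1.39 ± 0.53), a partner of Arntl, were higher. No gene passed over all genes in Flox (edgeR, smallest adjusted p = 0.0715, shared by Bhlhe40 and Dnaja1; 1129 at an unadjusted p under 0.05). DESeq2 called 44, 13 higher and 31 lower. The edgeR count was 1 without Flox labelled sedentary 3, Flox labelled exercise 1 or KO labelled exercise 2, and 2 without KO labelled exercise 3.

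**Figure D3:**
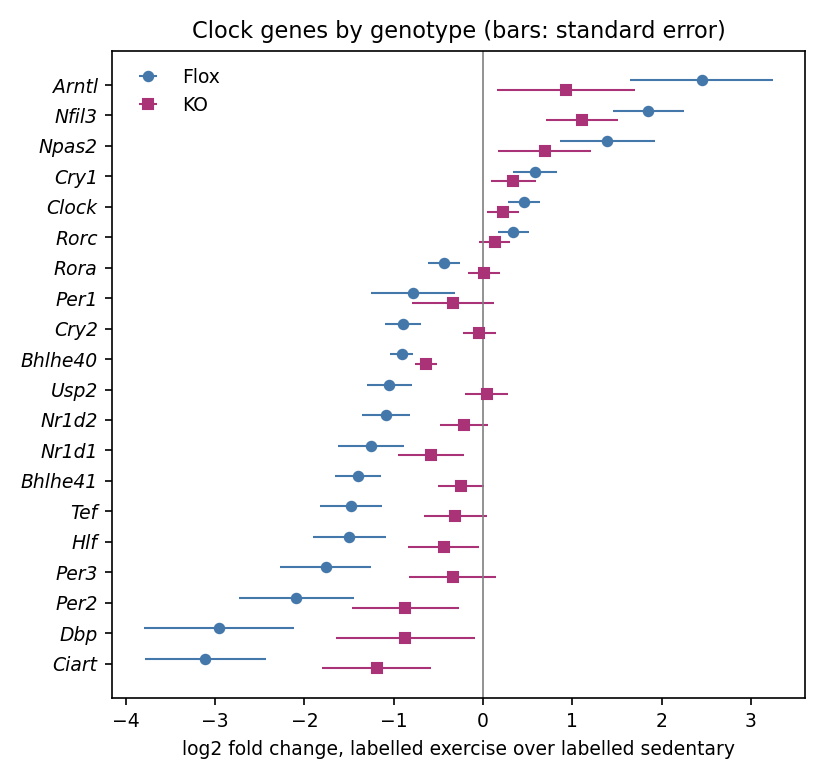
Log2 difference of each measured clock gene between libraries labelled exercise and labelled sedentary, in Flox and in KO; points are edgeR estimates and error bars standard errors. In Flox, Arntl lies at 2.45 and Dbp at -2.96; in KO the same genes lie at 0.93 and -0.87.

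Chaperone and matrix genes were higher in Flox hearts under the exercise label, and immune markers mainly in 1 library. Heat shock genes were higher in 19 of 22 members (median 0.27, camera adjusted p = 1.51e-06; adjusted p = 0.361 with an estimated correlation), 6 adjusted over the list alone and none over all genes. Dnaja1, a co-chaperone, stood at 89.7 ± 13.6 CPM against 47.5 ± 1.07 (0.92 ± 0.13, adjusted p = 0.0715), Hspa1a at 1.09 ± 0.29, Hspa8 at 0.54 ± 0.14 and Chordc1 at 0.56 ± 0.12. Genes of the unfolded protein response had a median of 0.31 (camera adjusted p = 0.000114; adjusted p = 0.361 with an estimated correlation), 7 higher adjusted over the list alone and none over all genes. Among them were the endoplasmic reticulum proteins Sdf2l1 (1.06 ± 0.28), Manf (0.89 ± 0.23) and Creld2 (0.69 ± 0.20) and the transcription factor Xbp1 (0.52 ± 0.15). Matrix genes were higher in 33 of 36 members (median 0.45, camera adjusted p = 1.28e-11; adjusted p = 0.361 with an estimated correlation), none passing adjusted over the list alone or over all genes. Thbs1 was at 1.55 ± 0.40, Col5a2 at 0.91 ± 0.25, Cilp at 1.06 ± 0.36, Col1a1 at 0.97 ± 0.33 and Col1a2 at 0.75 ± 0.27. In Flox labelled exercise Col1a1 stood at 127, 246 and 127 CPM, Col1a2 at 146, 282 and 174 and Col5a2 at 39.9, 76.2 and 40.8. Thbs1 was also highest in library 2, while Cilp was lowest there. Without that library the difference of the matrix list mean went from 0.53 to 0.40, and the list passed. Macrophage markers had a median of 0.64 (camera adjusted p = 7.35e-08), fibroblast markers 0.34 (7.63e-06) and neutrophil and platelet markers 0.76 (0.00307), each at an adjusted p = 0.534 with an estimated correlation. C1qa (0.64 ± 0.24) and Pf4 (1.18 ± 0.37) were among them. Without Flox labelled exercise 2, whose atrial mean was 6.56 against 2.74 and 2.91 in the other 2, the difference of the macrophage list mean went from 0.59 to 0.21. That of the neutrophil and platelet list went from 0.68 to 0.36, and the list no longer passed (camera adjusted p = 0.0779). The cell cycle list had a median of 0.52 (camera adjusted p = 0.0234; adjusted p = 0.982 with an estimated correlation), but without Flox labelled exercise 2 the median was -0.08 (camera adjusted p = 0.802). It did not pass without Flox labelled sedentary 2 (adjusted p = 0.206) or 3 (0.130) either. Cdc20, a mitotic gene, stood at 1.54, 4.05 and 2.22 CPM in Flox labelled exercise and Kif20a at 1.60, 3.47 and 1.94. The cyclin Ccnd2, at -0.51 ± 0.12, was the 1 member passing adjusted over the list alone. The respiratory chain list had a median of 0.10 (camera adjusted p = 0.0300; adjusted p = 0.982 with an estimated correlation), with Cox8b at 0.27 ± 0.19. It did not pass without Flox labelled sedentary 3 (median 0.02, adjusted p = 0.795) or Flox labelled exercise 3 (-0.05, 0.215).

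Lower in Flox under the exercise label were cardiomyocyte markers (median -0.10, camera adjusted p = 0.00764), calcium handling (-0.14, 0.00312), regulators of mitochondrial biogenesis (-0.12, 0.0208) and signalling through IGF1, AKT and mTOR (-0.10, 0.0162). Their adjusted p with an estimated correlation was 0.654, 0.654, 0.764 and 0.534. Each of these 4 calls was lost without some single library. The difference of the calcium handling list mean was -0.12, and ran from -0.25 without Flox labelled sedentary 1 to 0.02 without Flox labelled sedentary 3. That of IGF1, AKT and mTOR signalling was -0.05, and ran from -0.13 without Flox labelled sedentary 1 to 0.02 without Flox labelled sedentary 2. IGF1, AKT and mTOR signalling no longer passed without Flox labelled sedentary 2 or 3 or Flox labelled exercise 3 (adjusted p up to 0.195, median -0.08), and mitochondrial biogenesis without Flox labelled sedentary 2 or 3 or Flox labelled exercise 2 or 3 (adjusted p up to 0.192, median -0.07). Calcium handling no longer passed without Flox labelled sedentary 2 or Flox labelled exercise 3 (adjusted p up to 0.0923, median -0.11), and cardiomyocyte markers without Flox labelled exercise 2 (adjusted p = 0.286, median -0.04). The titin-binding Tcap was at -1.41 ± 0.47, the M-band protein Myom2 at -0.56 ± 0.18, Kcnh2 at -0.49 ± 0.18, Esrrb at -0.60 ± 0.17 and the transcription factor Foxo3 at -0.79 ± 0.21. Ddit4, an inhibitor of mTOR, was at 1.30 ± 0.35. Outside the lists, Pfkfb3, which drives glycolysis through fructose bisphosphate, was at -1.10 ± 0.21, the kinase Dyrk1b at -0.68 ± 0.13 and the septin Sept11 at 0.51 ± 0.11 (adjusted p = 0.399 each).

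In KO hearts, 3 genes were lower under the exercise label than under the sedentary label (edgeR; 1617 genes at an unadjusted p under 0.05; DESeq2 called 110). Clstn3 fell from 3.50 ± 2.12 to 0.191 ± 0.0795 CPM (-4.15 ± 0.50, adjusted p = 0.0195), Cidec from 11.5 ± 4.22 to 1.02 ± 0.231 (-3.48 ± 0.48, adjusted p = 0.0482) and Prkar2b from 13.8 ± 7.08 to 1.39 ± 0.324 (-3.30 ± 0.45, adjusted p = 0.0482). Clstn3 lies on chromosome 6 at 124430759 to 124464794 and Prkar2b on chromosome 12 at 31958476 to 32061296. Adipoq (-4.07 ± 0.58), Scd1 (-2.63 ± 0.36) and Acaca, the rate-limiting enzyme of fatty acid synthesis (-1.07 ± 0.18), came next without passing. This comparison, the genotype comparison under the sedentary label and the interaction share the same KO libraries labelled sedentary and are not independent. Adipocyte markers fell as a list (median -2.45, camera adjusted p = 1.66e-16; adjusted p = 0.125 with an estimated correlation), 1 member over all genes and 16 of 20 adjusted over the list alone, with 1 higher. Positive among single genes, none past the threshold, were the ephrin Efnb3 (1.02 ± 0.21), Phyhd1 (0.83 ± 0.18), Lsmem1 (0.68 ± 0.14) and Bcat2, which starts breakdown of branched-chain amino acids (0.63 ± 0.14). The count was 566 without KO labelled sedentary 1, 5 without Flox labelled sedentary 1 or Flox labelled exercise 2, and 6 without Flox labelled exercise 3 or KO labelled sedentary 2. It was 0 without Flox labelled sedentary 2, KO labelled sedentary 3 or any of the 3 KO libraries labelled exercise. It was 0 with the atrial marker mean as a covariate, where Clstn3 stood at -3.86 ± 0.56 (adjusted p = 0.210), and 0 with a term for libraries with vector reads, where it stood at -4.04 ± 0.53 (adjusted p = 0.0508).

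Metabolic and contractile lists were higher in KO under the exercise label. The atrial marker mean differed too, at 7.10 ± 1.38 log2 CPM under the sedentary label and 4.88 ± 2.03 under the exercise label. The differences of list means were not fitted with the atrial covariate in this comparison. The atrial share of the tissue is thus not separated from the treatment label here. The respiratory chain list was higher in 68 of 70 members (median 0.27, camera adjusted p = 1.66e-16; adjusted p = 0.443 with an estimated correlation), none passing over all genes or adjusted over the list alone. Atp5k was at 0.92 ± 0.23, Sdha at 0.50 ± 0.16 and Cox5a at 0.41 ± 0.14. Of the 13 mitochondrially encoded genes 4 were higher adjusted over the list alone and none over all genes (median 0.28, camera adjusted p = 3.18e-05; adjusted p = 0.443 with an estimated correlation). They included mt-Atp8 (1.02 ± 0.25), mt-Nd3 (0.69 ± 0.19) and mt-Atp6 (0.65 ± 0.19). Fatty acid oxidation had a median of 0.36 (camera adjusted p = 5.33e-10), glycolysis 0.23 (1.22e-05), mitochondrial biogenesis 0.22 (2.54e-05), calcium handling 0.22 (6.30e-05) and cardiomyocyte markers 0.24 (6.85e-06), each at an adjusted p = 0.443 with an estimated correlation. Members included Acadm (0.54 ± 0.17), Etfa (0.43 ± 0.14), Lpl (0.50 ± 0.14), Ldhb (0.44 ± 0.14) and the hexokinase Hk2 (0.52 ± 0.20). Others were the coactivator Ppargc1a (0.33 ± 0.14), Ryr2 (0.67 ± 0.25), Pln (0.48 ± 0.16), Myl2 (0.51 ± 0.19) and Myl3 (0.57 ± 0.23). Lower were atrial markers in 19 of 19 members (median -1.68, camera adjusted p = 6.85e-06), immediate early genes (-0.60, 1.22e-05), interferon response (-0.29, 0.000396), endothelial (-0.26, 0.00148), fibroblast (-0.17, 0.0343) and matrix genes (-0.14, 0.0160). With an estimated correlation these had adjusted p = 0.443, 0.443, 0.553, 0.501, 0.621 and 0.635. Nr2f2, an atrial transcription factor, was at -1.02 ± 0.31 and Jun at -0.49 ± 0.15. Without KO labelled sedentary 3 the difference of the immediate early list mean went from -0.58 to -0.15, though the list passed. Zfp36 stood at 21.9, 23.2 and 63.2 CPM in KO labelled sedentary and Dusp1 at 54.4, 52.1 and 95.2. Without KO labelled exercise 2, whose atrial mean was 2.56 against 6.30 and 5.79 in the other 2, the difference of the atrial list mean went from -2.22 to -1.06. For calcium handling the list mean differed by 0.07, by -0.08 without KO labelled exercise 1, by 0.01 without KO labelled sedentary 3, by 0.13 without KO labelled sedentary 1 and by 0.21 without KO labelled exercise 2. For fatty acid oxidation it went from 0.32 to 0.49 without KO labelled sedentary 1 or KO labelled exercise 3. For mitochondrial biogenesis it went from 0.23 to 0.37 without KO labelled sedentary 1 and to 0.14 without KO labelled sedentary 3. Matrix genes no longer passed without KO labelled sedentary 1 or KO labelled exercise 2 (adjusted p up to 0.740, median -0.03), and the interferon response without KO labelled sedentary 2 (adjusted p = 0.0603, median -0.17). Endothelial markers no longer passed without KO labelled exercise 3 (adjusted p = 0.105, median -0.17), and fibroblast markers without KO labelled sedentary 2 or 3 or KO labelled exercise 1 or 2 (adjusted p up to 0.506, median -0.05). The other 10 of 14 lists passed whichever library was left out. Ddx58 was at -0.44 ± 0.12, Eng at -0.79 ± 0.19, Ecscr at -0.57 ± 0.18, Tcf21 at -1.11 ± 0.24 and Bgn at -0.65 ± 0.19. Of the 20 clock genes, Bhlhe40 (-0.64 ± 0.12) passed adjusted over the list alone and the list itself did not (camera adjusted p = 0.278, median -0.23), with Nfil3 at 1.11 ± 0.40. Dbp stood at 103, 180 and 242 CPM in KO labelled sedentary and 76.9, 187 and 23.7 in KO labelled exercise, and Arntl at 10.7, 4.25 and 2.51 against 11, 3.05 and 19.1.

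The interaction asked whether the treatment labels differed by another amount in KO than in Flox. No gene passed (edgeR, smallest adjusted p = 0.279; 1505 at an unadjusted p under 0.05; DESeq2 called 47, 13 higher and 34 lower), with 2 without Flox labelled exercise 1 and 1 without KO labelled sedentary 2. Negative among the genes with the smallest p were Angpt2, a ligand of Tek (-1.48 ± 0.26), Adipoq (-5.52 ± 0.94) and Cebpa (-1.66 ± 0.30), and positive were Zfp971 (1.11 ± 0.20), Mb21d2 (0.86 ± 0.17), Slco5a1 (0.77 ± 0.18) and Sdr42e1 (1.06 ± 0.25). Lists for fat cells and matrix were lower in this contrast and metabolic lists higher, 11 lower and 9 higher by camera with the preset correlation. The smallest adjusted p with an estimated correlation was 0.428. All 36 matrix genes had a negative value (median -0.62, camera adjusted p = 3.67e-10; adjusted p = 0.428 with an estimated correlation), with Bgn at -0.90 ± 0.27 and Col5a2 at -1.03 ± 0.34. Adipocyte markers had a median of -2.60 (camera adjusted p = 1.35e-07; adjusted p = 0.428 with an estimated correlation), 11 lower and 1 higher adjusted over the list alone and none over all genes. Among them were Car3 (-4.45 ± 1.13), Cidec (-4.38 ± 0.83) and Scd1 (-2.52 ± 0.50). Further negative members of lower lists were Tcf21 (-1.43 ± 0.34), Eng (-1.07 ± 0.27), the natriuretic peptide Nppb (-1.74 ± 0.59), Fhl1 (-0.55 ± 0.16), Egr3 (-2.23 ± 0.87) and Psat1 (-0.99 ± 0.29). Positive members of higher lists were Acadm (0.63 ± 0.23), mt-Atp8 (1.12 ± 0.35), Hk2 (0.86 ± 0.28), Pdk1 (0.72 ± 0.22), Esrrb (0.92 ± 0.24), Tfb2m (0.53 ± 0.14) and Ryr2 (0.96 ± 0.36). So were Cacnb2 (0.65 ± 0.17), Foxo3 (1.13 ± 0.29), Insr (0.64 ± 0.21), Cry2 (0.86 ± 0.28), Bhlhe41 (1.14 ± 0.36) and Usp2 (1.09 ± 0.34). Clock genes that were higher in Flox under the exercise label had negative values, with Arntl at -1.52 ± 1.09, Npas2 at -0.70 ± 0.74 and Nfil3 at -0.73 ± 0.56. No clock gene passed adjusted over the list alone in this contrast. The atrial list itself had a median of -1.85 in this contrast. Whichever single library was left out, 13 of the 20 lists passed. Among these the list mean of immediate early genes went from -0.82 to -0.39 without KO labelled sedentary 3, that of macrophage markers from -0.69 to -0.31 without Flox labelled exercise 2 and that of the interferon response from -0.36 to -0.23 without Flox labelled sedentary 2. Calcium handling went from 0.19 to 0.04 without Flox labelled sedentary 3 or KO labelled exercise 1 and to 0.10 without Flox labelled exercise 3. It rose to 0.32, 0.29 and 0.33 without Flox labelled sedentary 1, Flox labelled exercise 2 and KO labelled exercise 2. The respiratory chain went from 0.18 to 0.11 and 0.10 without Flox or KO labelled exercise 2 and to 0.30 and 0.28 without Flox or KO labelled exercise 3, and fatty acid oxidation from 0.34 to 0.51 without KO labelled sedentary 1. The atrial list mean went from -2.43 to -1.19 without Flox labelled exercise 2 and to -1.27 without KO labelled exercise 2. Fetal and stress genes no longer passed without Flox labelled sedentary 1 or 2, Flox labelled exercise 1 or 3, KO labelled sedentary 1 or KO labelled exercise 1 or 2 (adjusted p up to 0.245, median -0.35), and IGF1, AKT and mTOR signalling without Flox labelled sedentary 2 or 3, Flox labelled exercise 1 or 3 or KO labelled exercise 1 or 3 (adjusted p up to 0.0926, median 0.12). Mitochondrially encoded genes no longer passed without Flox labelled exercise 2 (adjusted p = 0.0828, median 0.11), and the unfolded protein response without Flox labelled sedentary 1 or 2, Flox labelled exercise 2, KO labelled sedentary 1 or 3 or KO labelled exercise 2 (adjusted p up to 0.193, median -0.17). Atrial markers no longer passed without Flox labelled sedentary 1, Flox labelled exercise 2 or KO labelled exercise 2 (adjusted p up to 0.156, median -0.06), and endothelial markers without Flox labelled exercise 3 or KO labelled exercise 3 (adjusted p up to 0.113, median -0.08). Schwann and neuronal markers no longer passed without Flox labelled exercise 1 or KO labelled sedentary 2 (adjusted p up to 0.0741, median -0.28).

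**Figure D4:**
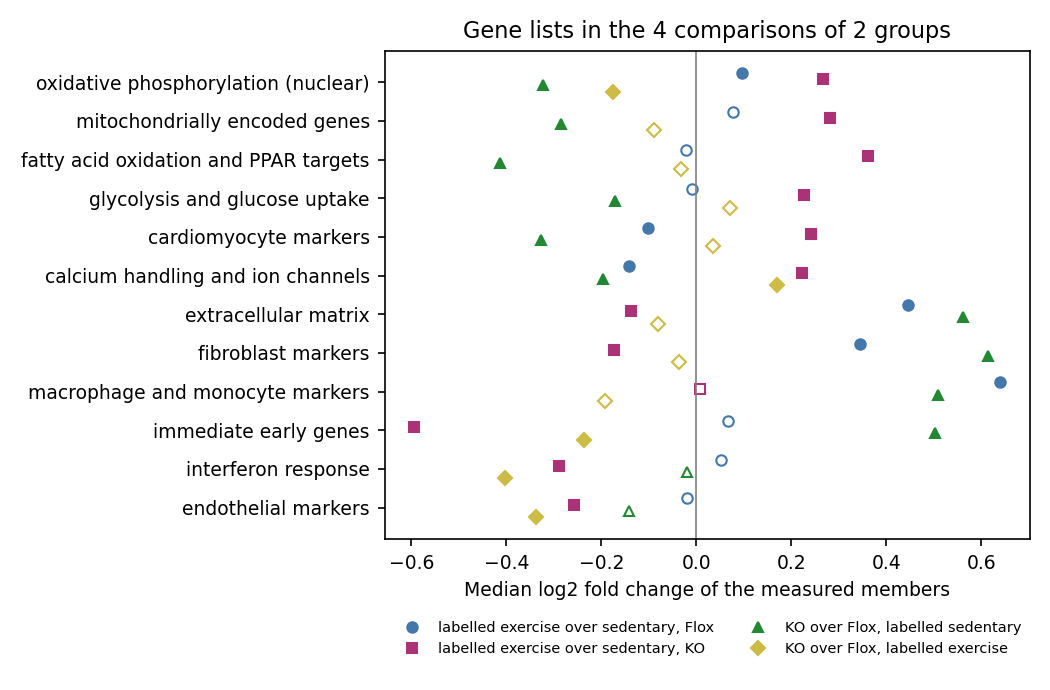
Median log2 difference of 12 gene lists in the 4 comparisons of 3 libraries with 3; filled symbols mark a camera adjusted p under 0.05 with the preset correlation and open symbols lists that did not pass. For KO over Flox under the sedentary label, fibroblast markers lie at 0.61 and the nuclear-encoded respiratory chain at -0.32.

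Averaged over genotype, 4 genes were lower under the exercise label and none higher (edgeR). Bhlhe40, a repressor in the clock, fell by 0.78 on the log2 scale (SE 0.09, adjusted p = 0.0103), from 66.6 ± 4.40 to 35.5 ± 3.56 CPM in Flox and from 67.6 ± 7.10 to 43.3 ± 6.47 in KO. The 6 libraries of each label did not overlap. Pfkfb3 fell 2.14-fold (adjusted p = 0.0387), the angiopoietin-like Angptl2 1.56-fold (adjusted p = 0.0460) and Clstn3 5.55-fold (adjusted p = 0.0486), the last at -0.80 in Flox and -4.15 in KO without passing the interaction. Bhlhe40 lies on chromosome 6 at 108660629 to 108666925, Pfkfb3 on chromosome 2 at 11471433 to 11554077 and Angptl2 on chromosome 2 at 33216069 to 33247717. The count was 12 without KO labelled sedentary 1 and 0 to 2 without any other single library except KO labelled sedentary 2, which gave 5. With the atrial marker mean or the vector-read term, Bhlhe40 alone passed (-0.79 ± 0.10 and -0.76 ± 0.09, adjusted p = 0.0306 and 0.0186). Of the lists, the clock had 5 higher and 12 lower adjusted over the list alone and 1 over all genes (camera adjusted p = 2.98e-05; adjusted p = 0.331 with an estimated correlation). Nfil3 was at 1.48 ± 0.28 and Ciart at -2.15 ± 0.46. Heat shock genes had a median of 0.20 (camera adjusted p = 1.36e-06; adjusted p = 0.482 with an estimated correlation), with Dnaja1 at 0.49 ± 0.09, Hspa8 at 0.43 ± 0.10 and Chordc1 at 0.41 ± 0.09. Unfolded protein response genes had a median of 0.15 (camera adjusted p = 0.000970; adjusted p = 0.490 with an estimated correlation), with Sdf2l1 at 0.80 ± 0.20 and Manf at 0.62 ± 0.17. All 70 respiratory chain genes had a positive value (median 0.17, camera adjusted p = 3.23e-15; adjusted p = 0.654 with an estimated correlation), with Atp5k at 0.60 ± 0.16. Mitochondrially encoded genes had a median of 0.14 (camera adjusted p = 0.000429; adjusted p = 0.654 with an estimated correlation), with mt-Nd3 at 0.56 ± 0.14 and mt-Atp6 at 0.51 ± 0.14. Adipocyte markers had a median of -0.97 (camera adjusted p = 1.24e-08; adjusted p = 0.331 with an estimated correlation), with Scd1 at -1.36 ± 0.25 and Acaca at -0.71 ± 0.13. Erythroid markers had a median of -0.18 (camera adjusted p = 0.00554; adjusted p = 0.654 with an estimated correlation), with Hba-a1 at -0.38 ± 0.10. Also higher were fatty acid oxidation (median 0.17, camera adjusted p = 2.60e-05), glycolysis (0.10, 0.00528), matrix (0.16, 0.00569), macrophage (0.27, 0.000970) and neutrophil and platelet lists (0.73, 0.00442). Lower were immediate early (-0.26, 0.0147), interferon (-0.09, 0.0460), atrial (-0.64, 0.00279) and endothelial lists (-0.10, 0.0460). With an estimated correlation the adjusted p was 0.654 for the neutrophil and platelet list and 0.742 for each of the others. The medians in Flox and KO were 0.45 and -0.14 for matrix, 0.64 and 0.01 for macrophage, 0.76 and 0.17 for neutrophil and platelet, -0.02 and 0.36 for fatty acid oxidation and -0.01 and 0.23 for glycolysis. They were 0.03 and -2.45 for adipocyte, 0.07 and -0.60 for immediate early, 0.05 and -0.29 for interferon, -0.17 and -1.68 for atrial, -0.02 and -0.26 for endothelial and -0.98 and -0.23 for clock genes. Heat shock genes were at 0.27 and 0.08, the unfolded protein response at 0.31 and 0.07, and the respiratory chain at 0.10 and 0.27. The mean of the mitochondrially encoded list went from 13.12 to 13.18 log2 CPM in Flox and from 12.77 to 13.11 in KO. The difference between the genotypes passed camera for these lists except neutrophil and platelet (adjusted p = 0.193) and heat shock (0.0860), and for none with an estimated correlation. Whichever library was left out, 7 of 16 lists passed here. Without Flox labelled exercise 3 the difference of the list mean went from 0.17 to 0.11 for the respiratory chain and from 0.20 to 0.13 for mitochondrially encoded genes. For fatty acid oxidation it went from 0.15 to 0.24 without KO labelled sedentary 1 or KO labelled exercise 3. Glycolysis no longer passed without KO labelled exercise 2 (adjusted p = 0.0582, median 0.07), and matrix genes without Flox labelled exercise 2 or KO labelled exercise 3 (adjusted p up to 0.370, median 0.08). Immediate early genes no longer passed without Flox labelled exercise 1, KO labelled sedentary 3 or KO labelled exercise 1 or 2 (adjusted p up to 0.417, median -0.04), and the interferon response without Flox labelled sedentary 1 or 3, Flox labelled exercise 1, KO labelled sedentary 2 or KO labelled exercise 1 or 2 (adjusted p up to 0.496, median -0.04). Atrial markers no longer passed without Flox labelled sedentary 3 or KO labelled exercise 2 (adjusted p up to 0.137, median -0.09), and endothelial markers without Flox labelled sedentary 1, Flox labelled exercise 2, KO labelled sedentary 1 or 2 or KO labelled exercise 3 (adjusted p up to 0.487, median -0.04). Macrophage markers no longer passed without Flox labelled exercise 2, KO labelled sedentary 1 or KO labelled exercise 3 (adjusted p up to 0.280, median 0.14), and neutrophil and platelet markers without Flox labelled exercise 2 or KO labelled exercise 3 (adjusted p up to 0.0543, median 0.34). Erythroid markers no longer passed without KO labelled sedentary 1 (adjusted p = 0.0778, median -0.17).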

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

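The tests of the adipocyte, clock and respiratory chain patterns were chosen only after those results had been seen, and the adipocyte batch test and both respiratory chain tests were rewritten after a first run. The batch and atrial tests of the clock were replaced later, with the values of the new tests already known, because both factors were close to even between the labels in Flox (2 of 3 libraries with vector reads under each, atrial means 0.21 apart) and the first tests had little room to come out otherwise; the exchange of the treatment words and the other splits of the samples were planned.

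Fat cell genes in the KO libraries labelled sedentary form the first pattern weighed. Of 20 adipocyte markers, 13 were higher in each of these 3 libraries than in all 9 others, and Ucp1 of brown fat stood at 22.8, 33.9 and 97 CPM against at most 3.9 elsewhere. The values argue against the vector-read batch as a whole cause: with a batch term the list difference was 2.52 ± 0.37 (2.59 ± 0.35 without it). The lowest atrial mean of the 3 was 5.54 log2 CPM, in KO labelled sedentary 1, whose adipocyte mean was 4.81. The 4 other libraries above that atrial mean had adipocyte means up to 2.67, against 4.58 to 5.32 in the 3. This argues against atrial tissue as a whole cause for KO labelled sedentary 1. KO labelled sedentary 2 and 3 had atrial means of 7.62 and 8.15, above every library of the other groups, so no library matches them. Fat tissue, taken along at dissection or part of the hearts, would give such a rise, but the count of 13 markers only restates it and is no evidence for fat tissue. Fat tissue and an effect of genotype in sedentary mice cannot be told apart, since all 3 libraries are one group.

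Clock genes between the treatment labels in Flox form the second. Among the libraries with vector reads 17 of 20 members passed adjusted over the list alone, and among the 4 Flox libraries of like low atrial mean (2.67 to 2.93) 17 had no overlap between the labels. Batch and atrial share were near even between the labels in Flox, and that balance argues against them as whole causes. The 2 counts add little to it. Each sets 2 Flox libraries of one label against 2 of the other, and no share over all genes was drawn beside them. The count by atrial mean also took its direction from the same libraries. All 14 of 14 members of the Arntl and Dbp phase sets moved in opposite directions, as a different time of day at collection would give. An effect of running on the clock could give that too, and the 2 cannot be told apart, because collection times are not given in the sources used here.

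Respiratory chain genes in the KO libraries labelled sedentary form the third. The batch term left the difference of the list mean at -0.37 ± 0.14, against -0.33 ± 0.13 without it, which argues against the vector-read batch. With the atrial marker mean as a covariate it was -0.20 ± 0.16, within 1 standard error of the value without it and within 2 of 0, so the atrial share of the tissue and the genotype cannot be told apart. Fewer ventricular cells, which the lower Myl2 and higher atrial markers could reflect, and an effect of genotype both stay open.

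Whether the treatment words of the labels were exchanged could not be settled from Cited4, whose log2 difference in Flox between the words was 0.56 (adjusted p = 0.735).

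Other splits of the samples gave the following numbers of genes. For KO over Flox averaged over treatment, 4 of 100 splits, the real one included, gave as many as the real 8, under the 5 set in advance. Cited4, whose loss defines the groups, is among the 8 and favours the real split. The highest other gave 227 with an atrial difference of 3.36 log2 CPM (real split 2.03). The count of 8 thus does not separate genotype from other differences between the samples, atrial share included. For the exercise average, 5 of 100 splits gave as many as the real 4, so chance is not excluded. The highest other gave 60 and set KO labelled exercise 2 with sedentary and KO labelled sedentary 1 with exercise libraries. For the interaction all 100 of 100 splits reached the real 0 (edgeR, 1505 genes at an unadjusted p under 0.05, DESeq2 47), as any split must, so that share tells nothing of chance. The highest other gave 210. The 10 of 10 splits given below for exercise in Flox also could not come out otherwise. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. There, the real count and the highest other were 0 and 0 for exercise in Flox (10 of 10 splits as large; edgeR, 1129 at an unadjusted p under 0.05; DESeq2 44), 3 and 4 for exercise in KO (3 of 10), 19 and 15 for genotype under the sedentary label (1 of 10), and 1 and 1 for genotype under the exercise label (3 of 10). The splits with 4 and with 15 genes follow the vector-read batch exactly. With the batch as a term the real counts were 0 and 13 (edgeR; 1617 and 2057 at an unadjusted p under 0.05 without the term; DESeq2 110 and 370).

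The interaction of genotype and treatment labels passed camera for 20 lists, and with an estimated correlation for none (adjusted p from 0.428 to 0.596). Lists with a negative median were adipocyte markers (-2.60, adjusted p = 1.35e-07), atrial markers (-1.85, 0.00434), immediate early genes (-0.74, 6.44e-05), macrophage markers (-0.73, 2.67e-05), matrix (-0.62, 3.67e-10), fetal and stress genes (-0.55, 0.0408), fibroblast markers (-0.53, 5.87e-06), Schwann and neuronal markers (-0.49, 0.0258), interferon response (-0.32, 0.000847), the unfolded protein response (-0.20, 0.0349) and endothelial markers (-0.20, 0.00520). Lists with a positive median were the clock (0.76, 0.00195), calcium handling (0.40, 1.24e-06), mitochondrial biogenesis (0.38, 5.81e-06), cardiomyocyte markers (0.37, 3.63e-07), fatty acid oxidation (0.33, 5.45e-07), glycolysis (0.28, 0.000180), mitochondrially encoded genes (0.26, 0.00943), the nuclear-encoded respiratory chain (0.17, 5.87e-06) and IGF1, AKT and mTOR signalling (0.17, 0.0305). Some rested much on 1 library: the list mean went from -0.82 to -0.39 for immediate early genes without KO labelled sedentary 3, and from -0.69 to -0.31 for macrophage and from -2.43 to -1.19 for atrial markers without Flox labelled exercise 2. For calcium handling it went from 0.19 to 0.04 without KO labelled exercise 1 or Flox labelled sedentary 3.

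Entries for cloning vectors, outside the gene tests, also held signal. The entry for pJG4-5 reached 1790 CPM, with 14311 to 32744 counts in 7 libraries (Flox labelled sedentary 2 and 3, Flox labelled exercise 1 and 3, KO labelled sedentary 1, KO labelled exercise 1 and 3) and 0 to 1 in the other 5. The highest levels for pBR322 and pHD-Amp were 32.4 and 7.26 CPM. The entry for pBK-CMV stood at 37.2 ± 5.67 CPM in KO (567 to 889 counts, n = 6) and 0.197 ± 0.161 in Flox (0 to 8 counts, n = 6).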

How the results depend on the processing

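Library totals alone, the vector-read term (alone or with the atrial covariate), the libraries with vector reads alone and the atrial covariate for lists were chosen only after the data had been seen; the other alternatives were planned. Cited4 passed for genotype under all of them. Of the named genes' values, those of Cited4 included, 2155 stayed on their side of the threshold, 130 moved past it, 116 no longer passed and 1 reversed: Hk2 for exercise in KO, at -0.03 with the vector-read libraries alone, where KO labelled sedentary is 1 library. With 1 library left out, 2505 stayed, 52 moved past and 143 no longer passed. Most named values did not pass in the main fit, and those that went on not passing count as having stayed. The 116 and 143 can come only from values that passed there, so the pooled counts overstate how stable the passing genes were. Numbers of genes below are in the order exercise in Flox, exercise in KO, genotype under the sedentary and under the exercise label, interaction, genotype average and exercise average (main values 0, 3, 19, 1, 0, 8 and 4). They were 2, 30, 120, 4, 1, 49 and 10 without a filter on low counts and 44, 110, 370, 10, 47, 158 and 46 with DESeq2. With 1 library left out they ran from 0 to 2, 0 to 566, 2 to 479, 1 to 2, 0 to 2, 4 to 34 and 0 to 12. The vector-read libraries alone gave 2, 6, 9, 3 and 1 for the first 5, of which 6, 9 and 1 rest on that 1 library and say nothing of stability, and the compared groups alone 2, 5 and 39 for the first 3. DESeq2's size factors gave 1 for exercise in KO and 2 for the exercise average, and library totals 36 for exercise in KO and 100 for genotype under the sedentary label. The replicate block gave 37 for genotype under the sedentary label, 19 for its average and 2 for the exercise average; replicate numbers paired libraries weakly (r from -0.32 to 0.31 over 18 pairs). The atrial covariate gave 0 for exercise in KO, 3 for genotype under the sedentary label, 2 for its average and 1 for the exercise average. The vector-read term gave 0 for exercise in KO, 16 for the genotype average and 1 for the exercise average, and both terms 0, 2 (genotype under the sedentary label), 1 and 1. With an estimated correlation 0 lists passed in each of the 7 comparisons, and 11 passed for the genotype average with the atrial covariate. Passing lists ran from 9 to 15, 13 to 17, 16 to 23, 4 to 14, 17 to 22, 13 to 21 and 13 to 19 with 1 library left out. Fewer samples or genes tested are part of the construction of some alternatives; for the rest the cause was not tested.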

Other observations

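All values in this part were looked up after the data had been seen. Of the 33 lists, 5 passed camera in no comparison with the preset correlation: CITED family and cardiac transcription factors, smooth muscle and pericyte, lymphocyte, neighbours of Cited4, and sex-linked genes. For the genotype average their medians were 0.04, 0.01, 0.01, 0.03 and -0.09. Ddx3y on the Y chromosome stood at 55 to 65 CPM in the 12 libraries. Besides Ucp1, Car3, a carbonic anhydrase abundant in fat, stood at 58.6, 56 and 109 CPM in KO labelled sedentary and at most 7.54 elsewhere. Of the 9 adipocyte markers with 10 CPM or more on average in the 9 other libraries, 3 (Scd1, Fasn and Acaca) were above all others in each KO library labelled sedentary and 6 were not. Among the 6, Fabp4, a fatty acid carrier, stood at 407, 486 and 512 CPM in KO labelled sedentary and 710, 492 and 513 in Flox labelled sedentary.

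Within KO, Dbp and Arntl levels in KO labelled sedentary 1 (103 and 10.7 CPM) and KO labelled exercise 2 (187 and 3.05) lay toward those of the other treatment label. These 2 libraries also differ from the others of their group in pJG4-5 counts, 16420 in the first and 0 in the second. Whether the 2 were exchanged was not settled, and an exchange would change each value that uses the KO groups. Their adipocyte means of 4.81 and 2.55 log2 CPM lay with their labelled groups (4.58 to 5.32 and 2.55 to 2.67). Between KO libraries, the split with these 2 exchanged gave 4 genes, against 3 for the labels, and in the exercise average it gave 60, against 4. Within KO that split follows the vector reads exactly, so the exchange and the library batch are not separated by these counts.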
